A study of Mus musculus with 24 samples.

How the data were processed

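The series holds ribosome profiling and RNA-seq of mouse liver from 2 lines of mice, each with a genomic deletion of a SECIS element in the 3′UTR of Selenop (selenoprotein P, ENSMUSG00000064373.12), and from wild type mice of each line. A SECIS element is an RNA structure that lets ribosomes read UGA as selenocysteine. Per the labels' protocols, footprints of about 30 nt were made with RNase I. Per the submitters' processing notes, reads were aligned with Bowtie, whose version is not given in the sources used here, to the mm9 build. The deposited table gives A-site counts, that is the number of footprints whose ribosomal A site was assigned to each nucleotide, for nucleotides 1 to 2096 of the Selenop mRNA and 12 ribosome profiling libraries. How the A site was assigned is not given in the sources used here. Per the file headers, a further table by the authors gives a ratio, the A-site counts scaled to all mapped footprints, divided by the Selenop RNA-seq reads scaled to all mapped RNA reads. Within a library this ratio equals the counts times a constant, so ratios of regions within a library are the same in both tables. It was used to compare levels between libraries. RNA-seq entered only through this ratio and was not analysed here on its own.

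Groups came from the labels: 3 SECIS1 wild type, 2 SECIS1 deletion, 3 SECIS2 wild type and 3 SECIS2 deletion libraries. A further library has a title that names no group, while its column heading calls it a SECIS1 deletion. It stayed out of all comparisons, which therefore used 11 libraries. No comparison was run with it included, and its values are given under the other observations. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. The 2 lines carry different sequencing request numbers, so line and batch cannot be told apart. The deletions were therefore compared through their differences from their own wild type. The alternative with pooled wild types gives both deletions the same control, so its difference between deletions includes line and batch. No pair of libraries in a group looked like the same library deposited again: the lowest chi-square per degree of freedom between replicates was 2.38.

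Total counts on Selenop ran from 17585 to 66070 per grouped library. Intervals on shares of counts are 95% exact Clopper-Pearson intervals, and a count of 0 was given a floor of 3 counts; both cover counting error only, since the reads carry no molecular identifiers in the tables used here.

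Coding positions were not given with the table and were set from the counts. The initiation peak, the position with most counts near the 5′ end, was nucleotide 158, which put the start codon at nucleotides from 155. UGA1, the first selenocysteine codon, was taken as codon 59 (nucleotides 329 to 331), a number fixed before the data were examined. The last covered codon was 378 (last nucleotide 1288), before the first run of 20 codons under 1% of the wild type count per codon upstream of UGA1. Codons 7 to 53 (nucleotides 173 to 313) formed the upstream part. Codons 65 to 373 formed the downstream part, split into a proximal part (codons 65 to 272, nucleotides 347 to 970) and a distal part (codons 273 to 373, nucleotides 971 to 1273). In each, 5 codons beside the start, UGA1 and the end were left out. The design had fixed that the downstream part would not be split if no annotation located the later UGA codons. The split was made all the same, by codon number and after the data were seen, so every statement on the proximal and distal parts is exploratory. The later UGA codons and the stop codon were not located, and their occupancy was not analysed here.

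Region counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test), with the upstream counts as library size, or the proximal counts for the distal part, all 4 groups in a group-means model with 7 residual degrees of freedom, and Benjamini-Hochberg adjustment over 16 region tests. Log2 fold changes are deletion over wild type. Codons were tested in the same way after edgeR's filterByExpr, as were windows of 10 codons, an addition made after the data were seen. Named codons are the 10 with the largest absolute log2 fold change among those past an adjusted p of 0.05, 5 higher and 5 lower where both exist, with the start codon and UGA1. Levels and occupancies were tested with exact two-sided permutation tests, which cannot go below 0.1 with these group sizes. On simulated counts for 258 codons with 60 changed, the SECIS2 codon test recovered 9.33% of changes at 2-fold and 83.3% at 4-fold, with 1.43% and 4.60% of calls wrong, so a codon that was not called may still differ.

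Alternatives were no codons or 10 codons left out, all counts as library size, DESeq2 1.42.0, only the compared groups in the fit, a replicate block, each library left out, the 5 highest positions left out, the authors' ratio, pooled wild types, and for codons TMM, DESeq2, no filter and bins of 5 codons. Replicate numbers were checked for pairing by correlating deviations from group means over codons. In the SECIS2 line same-numbered libraries gave 0.390, 0.115 and 0.163, which met the criterion for pairing, with no label that states its source. In the SECIS1 line they gave -0.053 and -0.014.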

Results

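Ribosome profiling of mouse liver was used to follow ribosomes along the mRNA of Selenop (ENSMUSG00000064373.12), the plasma selenium carrier, whose reading frame holds several UGA codons read as selenocysteine and whose 3′UTR holds the elements SECIS1 and SECIS2. The comparisons ask how each element affects initiation and the passage of ribosomes through UGA codons. Total A-site counts were 66070, 55710 and 34061 in the SECIS1 wild type libraries, 23331 and 22077 in the SECIS1 deletion, 40721, 17585 and 31140 in the SECIS2 wild type, and 25334, 27231 and 22041 in the SECIS2 deletion. Among coding counts, 56.2% ± 3.63 (SD, n = 3) lay in the first frame position in SECIS1 wild type and 57.7% ± 6.27 (SD, n = 3) in SECIS2 wild type libraries.

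Deletion of SECIS2 lowered ribosome density downstream of UGA1, while deletion of SECIS1 left its average over the whole downstream part within the spread between libraries. The ratio of density downstream to upstream of codon 59 was 0.554 ± 0.052 (SD, n = 3) in SECIS2 wild type and 0.282 ± 0.00269 (SD, n = 3) in the SECIS2 deletion, a 1.97-fold decrease. The log2 change was -0.98 (SE 0.12, 95% interval -1.25 to -0.70, edgeR adjusted p = 0.000152), and all 3 deletion libraries lay below all 3 wild type libraries. The exact permutation p was 0.1, the smallest that 3 against 3 allow. In the SECIS1 line the ratio was 0.402 ± 0.0574 (SD, n = 3) in wild type and 0.395 ± 0.0133 (SD, n = 2) in the deletion, a log2 change of -0.03 (SE 0.13, 95% interval -0.34 to 0.28, edgeR adjusted p = 0.849). This average holds a proximal change of 0.20 (SE 0.14) and a distal change of -2.07 (SE 0.19), both against the upstream part. The difference between both deletions was 0.95 on the log2 scale (SE 0.17, edgeR adjusted p = 0.00177), and 1.29 (SE 0.18) for the proximal part alone. With all counts on the mRNA as library size, the SECIS2 value was -0.074 and was not called. That value is downstream counts per count on the mRNA, not the downstream to upstream ratio. Its scale includes nucleotides 1530 to 1703 of the 3′UTR, which held 4.81% to 47.6% of the counts of SECIS2 wild type libraries. For the downstream part, the difference between deletions also fell short of the threshold with that library size (0.68), with the 5 highest positions per region left out (0.93, adjusted p = 0.066) and with pooled wild types (0.49, adjusted p = 0.0987). The value with pooled wild types includes line and batch.

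**Figure D1:**
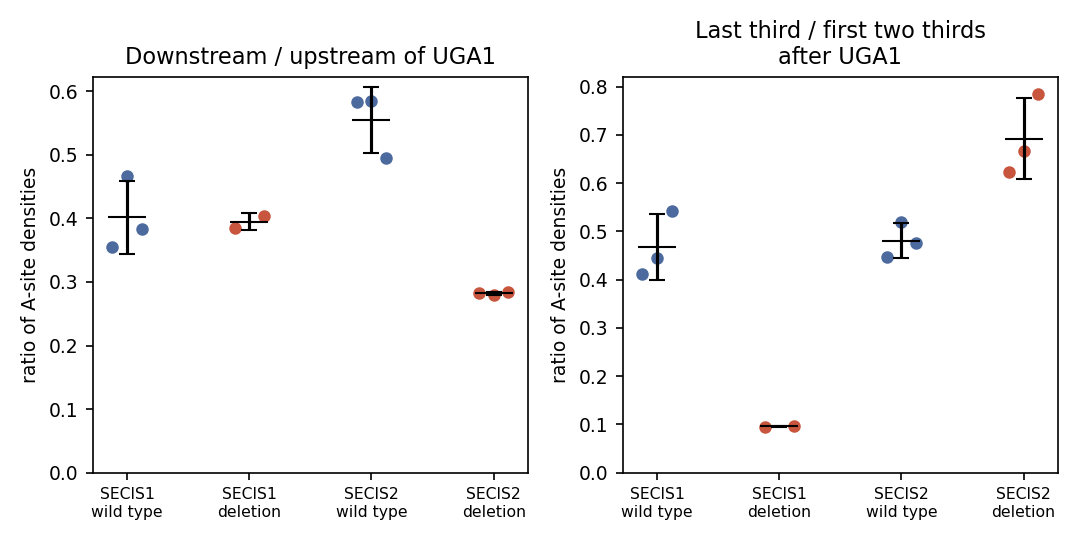
Ratios of A-site densities per library (points) with group mean and SD (bars), for the downstream part over the upstream part (left) and the distal over the proximal part (right). SECIS2 deletion libraries lie at 0.279 to 0.284 on the left, below all SECIS2 wild type libraries, and SECIS1 deletion libraries at 0.0955 and 0.0965 on the right.

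Along the mRNA, the decrease in the SECIS2 deletion started at UGA1. In windows of 10 codons the log2 change was -0.01 (SE 0.19) at codons 51 to 60 and -1.95 (SE 0.24, edgeR adjusted p = 3.75e-06) at codons 61 to 70. The latter window holds codon 63, with 637, 289 and 972 counts in SECIS2 wild type and 277, 150 and 100 in the deletion. It was also lower in SECIS1 than in SECIS2 wild type, at -1.06 (SE 0.23, edgeR adjusted p = 0.00445). Codons 71 to 80 changed by -1.24 (SE 0.25) in the SECIS2 deletion and differed by -0.74 (SE 0.24) between the wild types. Of 21 windows from codon 61 to 270, 20 fell, with a median log2 change of -1.14. Codons 1 to 10, which hold the initiation peak at codon 2, rose by 0.65 (SE 0.28, edgeR adjusted p = 0.0435). They were the 1 window that rose, and with the replicate block 3 did. A single step fitted to the ratio of deletion to wild type fell after codon 59, and in 8 of 9 pairs of libraries it fell within 5 codons of it.

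**Figure D2:**
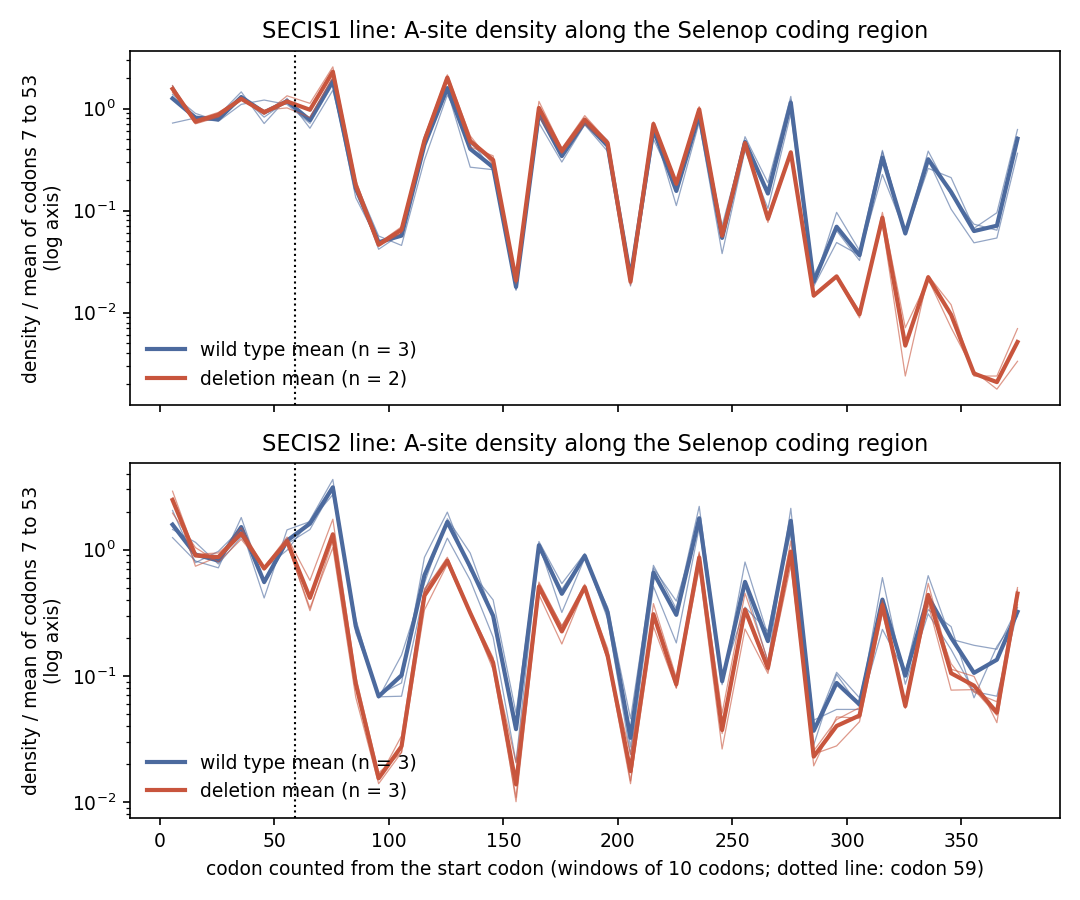
A-site density in windows of 10 codons, divided by the mean of codons 7 to 53 (log axis), for each library (thin lines) and group mean (thick lines); the dotted line marks codon 59. In the SECIS2 line the curves part after codon 59, and in the SECIS1 line they part beyond codon 270.

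Deletion of SECIS1 lowered ribosome density in the distal part of the reading frame. The ratio of distal to proximal density was 0.467 ± 0.0684 (SD, n = 3) in SECIS1 wild type and 0.0960 ± 0.000641 (SD, n = 2) in the deletion, 4.86-fold lower. The log2 change was -2.28 (SE 0.15, edgeR adjusted p = 5.42e-06), and both deletion libraries lay below all 3 wild type libraries. In the SECIS2 line the same ratio rose 1.44-fold, from 0.481 ± 0.0363 (SD, n = 3) to 0.692 ± 0.0841 (SD, n = 3), a log2 change of 0.53 (SE 0.12, edgeR adjusted p = 0.00698). Against the upstream part, average distal density in the SECIS2 deletion was still lower, at -0.57 (SE 0.15), beside -1.09 (SE 0.12) for the proximal part. This decrease was uneven: of the 11 windows from codon 271, 6 fell and 5 were not called. Window values ran from -1.36 (SE 0.34) at codons 361 to 370 to 0.47 (SE 0.24, edgeR adjusted p = 0.0900) at codons 371 to 378. That last window reaches past codon 373, where the distal part ends. In it all SECIS2 deletion libraries lay above all SECIS2 wild type libraries. The difference between the deletions in the ratio of distal to proximal density was -2.81 (SE 0.19, edgeR adjusted p = 5.42e-06). With the distal part starting at the midpoint of the downstream codons, a choice made after seeing the data, the SECIS1 change was -1.02 (2.03-fold lower) and the difference -1.37, both still called, and the SECIS2 rise of 0.35 was not called (adjusted p = 0.157). With all counts as library size, distal counts per count on the mRNA changed by -1.44 (2.72-fold lower) in the SECIS1 deletion. The difference was -1.77. Both were called, and the SECIS2 value of 0.32 was not. These values are not ratios to the proximal part.

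The loss in the SECIS1 deletion deepened towards the end of the reading frame. No window up to codon 270 was called. The log2 change was -0.82 (SE 0.33, edgeR adjusted p = 0.0773) at codons 261 to 270, -1.62 (SE 0.26) at codons 271 to 280, -3.66 (SE 0.39) at codons 321 to 330 and -6.56 (SE 0.43, edgeR adjusted p = 5.80e-10) at codons 371 to 378. Of the 11 windows from codon 271, 10 fell; codons 281 to 290 were at -0.44 (SE 0.26).

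**Figure D3:**
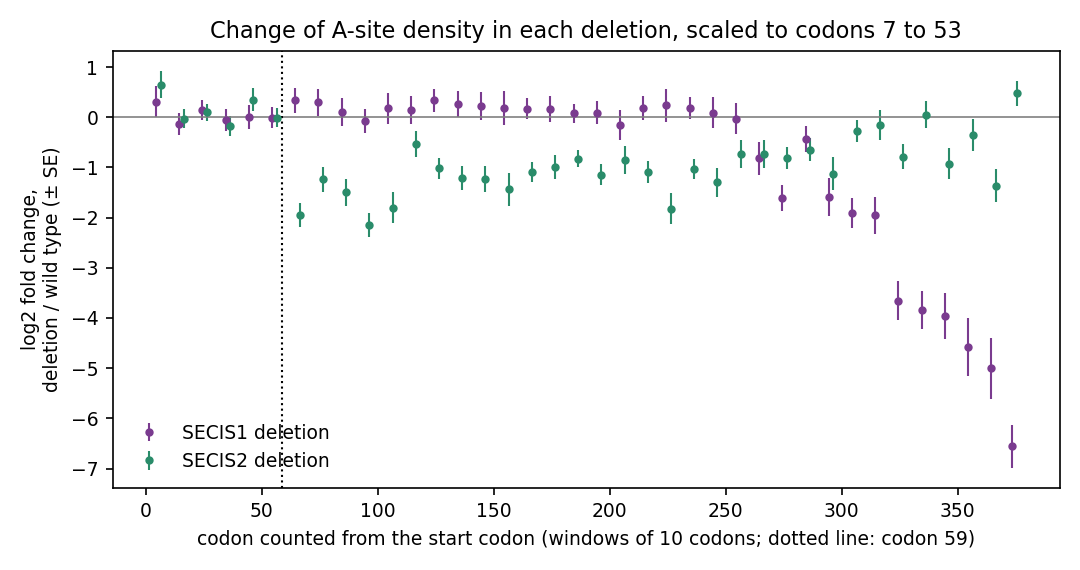
Log2 fold change of A-site density, deletion over wild type, in windows of 10 codons, scaled to codons 7 to 53; bars are SE and the dotted line marks codon 59. SECIS1 deletion values stay near 0 up to codon 260 and reach -6.56 at codons 371 to 378, whereas SECIS2 deletion values drop to -1.95 at codons 61 to 70.

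At single codons, 258 were tested. In the SECIS1 deletion 38 fell, 37 of them at codons 273 to 378, and 0 rose in edgeR (5 at an unadjusted p under 0.05, 0 with DESeq2, 2 with only the compared groups in the fit). The largest decreases were at codons 377 (log2 change -7.16, SE 0.71), 375 (-7.11, SE 0.62) and 376 (-6.91, SE 0.70); codon 377 held 141, 130 and 111 counts in wild type and 1 and 0 in the deletion. By counts alone codon 377 was 160-fold lower per upstream count (exact counting interval 28.5 to 6328), and codon 375, with 2 counts in the deletion, 139-fold (38.4 to 1153). Codon 374, with 1 count in the deletion, was also named by the rule. At codons 342, 366, 367, 352, 326 and 323 both deletion libraries had 0 counts, so their fitted changes and rank depend on the model; with a floor of 3 counts per library they were at least 2.34-fold (codon 323) to at least 3.63-fold (codon 342) lower. Without deletion replicate 2 or deletion replicate 3, 23 and 24 codons fell. In the SECIS2 deletion 95 codons fell, 84 of them at codons 60 to 272, and 3 rose, codons 6, 3 and 49, by 1.41, 1.17 and 1.12. The lower ones named by the rule included codons 180 (-3.29, SE 1.10), 108 (-3.28, SE 0.56) and 241 (-3.11, SE 0.89). This split depended on the scaling. TMM moved the median log2 change from -0.90 to -0.03 and gave 20 higher and 7 lower codons, and DESeq2 size factors gave 19 higher and 10 lower. Both scalings take most codons as unchanged, although 152 of the tested codons lie at codons 60 to 272 and 53 beyond. They are built to bring the median near 0, so they cannot tell a general decrease after codon 59 from rises before it. With the replicate block 8 codons rose. Without deletion replicate 1 or deletion replicate 2, 59 and 49 fell; 7 rose without wild type replicate 3, and 0 without deletion replicate 2.

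The effects of both deletions differed at 81 codons. At 51 of these, all between codons 60 and 272, the SECIS1 effect was the higher, and at 30, all between codons 273 and 378, it was the lower. TMM gave 6 higher and 43 lower, and DESeq2 gave 9 and 40, with the same limit of both scalings. Codons 376, 377 and 375 had the lowest differences among them (-7.87, -7.84 and -7.38) and codons 174 and 108 the highest (4.13 and 4.08). Leaving out SECIS1 deletion replicate 2 gave 18 higher and 14 lower, SECIS1 deletion replicate 3 gave 20 and 18, and the number higher was 33, 27 and 33 without SECIS2 deletion replicates 1, 2 and 3.

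Around initiation, the SECIS2 deletion was higher at codons 1 to 10 and at codons 3 and 6, as given above. That window holds the codon 2 peak, so it is not separate evidence from it. Its libraries overlapped, with SECIS2 wild type replicate 2 at 2.04 times the upstream mean and deletion replicate 1 at 1.95. The level upstream of UGA1 had only exact permutation tests, which cannot go below 0.1 here, so they could not pass the threshold. Permutation tests of the occupancy of codon 2 and of UGA1 share that limit. In the edgeR codon test neither codon was called in either line. Adjusted p was 0.989 (SECIS1) and 0.191 (SECIS2) at codon 2, and 0.799 and 0.710 at UGA1. The authors' ratio summed upstream was 0.0764 ± 0.0121 (SD, n = 3) in SECIS1 wild type and 0.0828 ± 0.000713 (SD, n = 2) in the deletion, an exact permutation p of 0.8. In the SECIS2 line it was 0.0486 ± 0.000684 (SD, n = 3) and 0.0522 ± 0.00308 (SD, n = 3), an exact permutation p of 0.3. At the initiation peak, codon 2, occupancy over the upstream mean was 11.5 ± 4.37 (SD, n = 3) in SECIS2 wild type and 18.1 ± 4.16 (SD, n = 3) in the deletion (exact permutation p = 0.2). It was higher in the deletion in all 3 pairs of same-numbered SECIS2 libraries, for which the exact paired p of 0.25 is the smallest possible. In the SECIS1 line it was 9.32 ± 5.17 (SD, n = 3) and 10.4 ± 2.02 (SD, n = 2) (exact permutation p = 0.9; log2 difference 0.34, and -0.21 without wild type replicate 1). At UGA1 itself it was 0.388 ± 0.0393 (SD, n = 3) and 0.349 ± 0.0343 (SD, n = 3) in the SECIS2 line (exact permutation p = 0.3), and 0.438 ± 0.0189 (SD, n = 3) and 0.335 ± 0.0794 (SD, n = 2) in the SECIS1 line (exact permutation p = 0.1, the smallest possible). With 1 codon on each side included, the log2 difference moved from -0.15 to -0.69 in the SECIS2 line (exact permutation p = 0.1, all libraries separated) and from -0.40 to -0.11 in the SECIS1 line (exact permutation p = 0.7). The start codon's own log2 change was 0.29 (SE 0.69) in the SECIS1 and -1.18 (SE 0.64) in the SECIS2 deletion (edgeR adjusted p = 0.989 and 0.144). Counts in the 5′UTR changed by 0.21 (SE 0.48) and 0.44 (SE 0.43), neither past the threshold (edgeR adjusted p = 0.788 and 0.481). With all counts as library size the SECIS2 value was 1.43 and was called (edgeR adjusted p = 0.00365). That value is 5′UTR counts per count on the mRNA. Its scale includes the downstream part, which fell in the SECIS2 deletion, and nucleotides 1530 to 1703 of the 3′UTR. It therefore does not show a rise against the upstream part.

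A peak of counts in the 3′UTR of wild type libraries was missing from the SECIS1 deletion. At nucleotides 1645 to 1647, around the highest 3′UTR position of the wild type libraries, SECIS1 wild type libraries had 13002, 17623 and 9222 counts and the deletion libraries 0 and 0; a count of 0 allows up to 0.0136% of the total. The run without counts in both deletion libraries reached from nucleotide 1530 to 1703. These bounds were set from the absence itself, so the run describes it and does not test it, and if the deleted sequence covers it no read could fall there; the position of the deletion on the mRNA is not given in the sources used here. In that run the wild type libraries of the line had 16563, 21105 and 10739 counts, or 25.1%, 37.9% and 31.5% of their totals (95% exact intervals within ± 0.724 percentage points). All counts after the last covered codon, per upstream count, fell by 8.34 on the log2 scale in the SECIS1 deletion (SE 1.45, edgeR adjusted p = 0.00147), a fitted value that depends on few counts. Without the 5 highest positions it was -4.88 (29.5-fold lower), and the difference between the deletions -5.58, both still called. These values still hold the rest of the run from nucleotide 1530 to 1703, so they largely restate its absence. Outside the run, SECIS1 counts per upstream count changed by -2.22 before it (exact permutation p = 0.1, the smallest possible). After the run they changed by -0.66 (exact permutation p = 0.2). In the SECIS2 line all counts after the last covered codon, per upstream count, changed by -1.71 on the log2 scale (SE 0.88, edgeR adjusted p = 0.156). This change was called with DESeq2 (adjusted p = 0.0295) and without SECIS2 wild type replicate 3, at -2.25 (adjusted p = 0.00204). It turned to 0.69 without the 5 highest positions. With all counts as library size the value was -0.49 and was not called. SECIS2 wild type replicate 3 held 1498 counts in the run from nucleotide 1530 to 1703, 4.81% of its total. The other SECIS2 wild type libraries held 19392 and 6865 there, and the SECIS2 deletion libraries 4056, 4280 and 5894. For all counts after the last covered codon, the difference between the deletions was -6.63 (edgeR adjusted p = 0.00547), and it too includes the run.

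**Figure D4:**
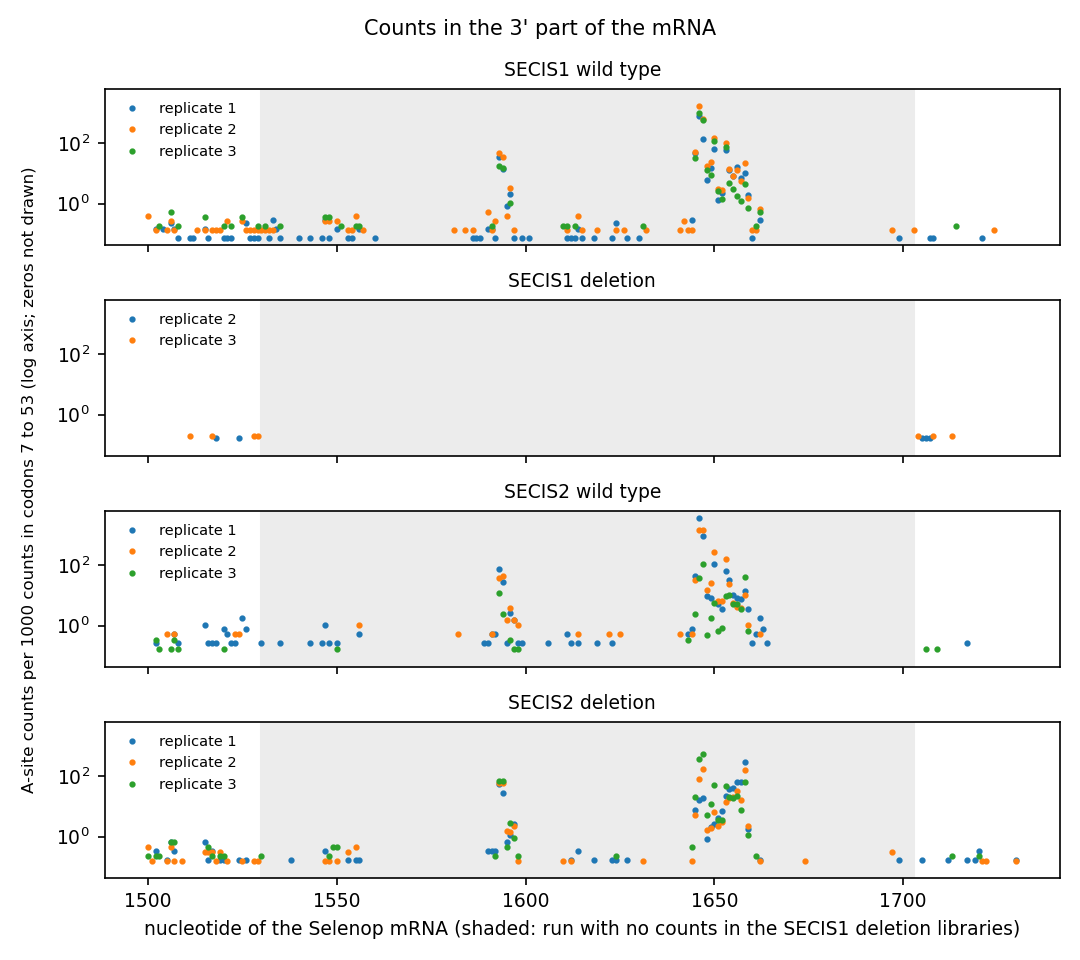
A-site counts per 1000 upstream counts (log axis, zeros not drawn) at nucleotides of the 3′UTR, 1 panel per group and 1 colour per replicate; shading marks nucleotides 1530 to 1703. The peak at nucleotide 1646 appears in wild type libraries and no point lies in the shaded region of the SECIS1 deletion. SECIS2 deletion libraries also have counts in the shaded region. SECIS2 wild type replicate 3 had 232 counts at nucleotide 1646 and 240 at nucleotide 1658.

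The wild type libraries of both lines, which share a genotype by label but not a sequencing request, differed too. Density downstream of UGA1 relative to upstream was 1.38-fold lower in the SECIS1 line, a log2 difference of -0.46 (SE 0.12, edgeR adjusted p = 0.00786), and 10 codons were lower and 2 higher, among them codon 63 (-2.51, SE 0.37) and codon 44 (1.78, SE 0.44). In windows of 10 codons, 13 of 38 were lower and 2 higher in the SECIS1 line. The distal ratio differed by -0.04 (SE 0.12, edgeR adjusted p = 0.788). The authors' ratio upstream of UGA1 was 1.56-fold higher in the SECIS1 line (exact permutation p = 0.1, the smallest possible). The difference in the ratio of downstream to upstream density was not called with DESeq2 (adjusted p = 0.117) or the 5 highest positions left out (-0.39). Downstream counts per count on the mRNA, with all counts as library size, differed by -0.14 and were not called. The number of lower codons was 2 without SECIS1 wild type replicate 1 or replicate 2, and 25, 4 and 31 without SECIS2 wild type replicates 1, 2 and 3; the number higher ran from 0 to 7.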

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

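All tests of explanations below were chosen after the results were seen, except the comparisons of splits of the libraries. Several results differ between both deletions by a test of the difference itself. These are density downstream of UGA1 (0.95 on the log2 scale), the ratio of distal to proximal density (-2.81), counts after the last covered codon (-6.63) and 81 codons. Counts after the last covered codon include the run from nucleotide 1530 to 1703, whose bounds were set from its absence in the SECIS1 deletion.

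The SECIS2 deletion had lower density downstream of UGA1. More footprints upstream with no loss downstream is argued against by the authors' ratio summed downstream, which fell by 0.87 (SE 0.11). A drift along the mRNA is argued against by the later proximal codons, which changed by 0.15 (SE 0.22) against the earlier ones, away from the fall that a drift needs. Without the 5 highest positions per region the change was -0.92 (SE 0.25, edgeR adjusted p = 0.0101), which argues against these positions as its whole cause; its error leaves open that they account for part of it. A biological effect of the deletion on UGA1 readthrough therefore stays a hypothesis; of the 10 splits of the libraries, the real one gave 98 codons and the highest other 0, also among the 4 that part all pairs, and 10 splits are too few for a share under 0.05, as the 1 split as large as the real one, itself, already exceeds it.

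The SECIS1 deletion had lower distal density. A few strong positions are argued against, since the change without the 5 highest was -2.25 (SE 0.13). For an mRNA that lacks its 3′ part, or loss of 3′ reads, the end of the reading frame was set against the counts beyond nucleotide 1703. The log2 change beyond nucleotide 1703 lay 5.88 (SE 0.91) above that of codons 371 to 378. The deletion libraries held only 7 and 3 counts at those codons and 20 and 29 beyond. Of the latter, 6 and 12 lay in the cluster at nucleotides 2009 to 2033. The gap argues against such a loss at the end of the frame only if the counts beyond come from this mRNA. Their origin was not tested, and a constant background would leave the same gap. Counts beyond nucleotide 1703 per proximal count changed by -0.85 (SE 0.39), and those between the last covered codon and nucleotide 1530, per upstream count, by -2.22 (3 and 15 counts in the deletion; exact permutation p = 0.1, the smallest possible), so such a loss stays open for the average distal change. RNA coverage was not analysed here, so a biological loss of passage through later UGA codons is a hypothesis that these counts alone do not settle.

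The 3′UTR peak was missing from the SECIS1 deletion, which follows of itself if the deleted sequence holds it. Depth does not account for the spread among SECIS2 wild type libraries, whose counts at nucleotides 1530 to 1703 per upstream count differed 20.3-fold. A candidate explanation is protection of the RNA at the peak from the nuclease, by its structure or a bound protein. This was not tested, nor were ribosomes in the 3′UTR or an origin of the reads at another locus. Whether the peak lies on SECIS1 is not given in the sources used here.

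Between the wild type libraries of both lines, 12 codons differed, and 2 of the 10 splits gave as many, the highest other giving 12; these splits are too few for a share under 0.05.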

How the results depend on the processing

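Of the tested values under the alternatives, 259 kept direction and side of the threshold, 24 reversed, 14 lost and 3 gained the call. Among counts of codons or windows, 64 stayed within 1.5 times and 40 did not. The upstream level and the occupancies of codon 2 and UGA1 had exact permutation tests, which cannot reach the threshold here. Their side of it was fixed in advance, so only their direction could change. Unless stated, the cause was not tested. In this section readthrough names the ratio of downstream to upstream density, and distal passage the ratio of distal to proximal density. Both are ratios of counts, and passage itself was not measured. All counts as library size set each part against the whole mRNA rather than against the upstream or proximal part. This gave 0.60 (SECIS1), -0.074 (SECIS2), 0.68 (difference) and -0.14 (wild types) for the downstream part. It gave 0.32 for the SECIS2 distal part, 1.43 for the SECIS2 5′UTR, and 0.057 (wild types) and -0.49 (SECIS2) for the 3′ counts. DESeq2 gave -0.46 for wild type readthrough (adjusted p = 0.117) and -1.71 for the SECIS2 3′ counts. Without the 5 highest positions, readthrough was 0.0060 (SECIS1), 0.93 (difference) and -0.39 (wild types), the 5′UTR -0.36 (SECIS2) and 1.02 (difference), and the 3′ counts 0.69 (SECIS2) and 0.011 (wild types). The midpoint split, chosen after seeing the data, gave 0.35 for SECIS2 distal passage. Pooled wild types, which bring line and batch into each comparison, gave 0.49 for the readthrough difference and -0.16 for the SECIS1 5′UTR. With no codons left out, wild type distal passage was 0.14. The authors' ratio gave -0.97 and -0.47 for SECIS2 and wild type readthrough, and -2.27 and 0.52 for distal passage. For the 3′ counts it gave -8.37 (SECIS1) and 0.18 (wild types). Here the exact test cannot go below 0.1, so neither lost calls nor values that stayed uncalled say anything about stability. The whole reading frame in place of the upstream part gave -0.47 for the SECIS2 level, since it holds the downstream part.

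Codon counts were, with TMM, 20 higher and 7 lower (SECIS2), 6 higher (difference) and 4 lower (wild types); with DESeq2, 19 and 10 (SECIS2), 9 higher (difference) and 7 higher (wild types); in bins of 5 codons, which are fewer, 18 lower (SECIS1), 39 lower (SECIS2), 31 higher and 16 lower (difference) and 1 higher (wild types); with only the compared groups, 2 higher (SECIS1).

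In the replicate block, 8 codons and 3 windows were higher in SECIS2, and the SECIS1 initiation peak was -0.21; no region test changed its call, and the other counts of codons and windows stayed within 1.5 times. The block on windows was added after seeing the data. SECIS1 libraries share only a number.

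Leaving out each library gave, for readthrough, -0.11 to 0.095 (SECIS1), -1.05 to -0.93 (SECIS2), 0.87 to 1.07 (difference) and -0.58 to -0.38 (wild types); for distal passage, -2.36 to -2.16, 0.42 to 0.60, -2.89 to -2.68 and -0.17 to 0.041; for the 5′UTR, -0.33 to 0.63, 0.15 to 0.75, -0.77 to 0.19 and -1.15 to -0.42; for the 3′ counts, -8.98 to -7.89, -2.25 to -1.10, -7.28 to -6.10 and -1.12 to 0.035; for codons higher, 0 to 0, 0 to 7, 18 to 71 and 0 to 7; for codons lower, 23 to 36, 49 to 107, 14 to 33 and 2 to 31. The SECIS1 upstream level ran from -0.0085 to 0.21 and its initiation peak from -0.21 to 0.73. Where this left 1 SECIS1 deletion library, it was assumed to vary like the other groups. The distal part ending at the last UGA codon and the later UGA and stop codons were not run, as these were not located.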

Other observations

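The library whose title names no group carries a column heading in the deposited table that calls it a SECIS1 deletion. It had 27317 counts, 1 of them at nucleotides 1530 to 1703. The SECIS1 deletion libraries held 0 and 0 there, and each other grouped library 1498 or more. Its density ratio was 0.316 downstream to upstream of UGA1, below SECIS1 deletion (0.385 and 0.404) and SECIS1 wild type libraries (0.356 to 0.466). Distal to proximal it was 0.140, beside 0.0955 and 0.0965 in SECIS1 deletion and 0.411 to 0.543 in SECIS1 wild type. If it is a SECIS1 deletion, the SD of the distal ratio from 2 libraries is too small. Its initiation peak stood at 3.52 times the upstream mean.

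Towards the 3′ end, nucleotides 2009 to 2033 held a smaller cluster of counts, highest at nucleotide 2021. The counts were 46, 15 and 11 in SECIS1 wild type, 6 and 12 in the SECIS1 deletion, 15, 5 and 1 in SECIS2 wild type and 2, 0 and 2 in the SECIS2 deletion. Per 1000 upstream counts, SECIS2 wild type replicate 3 (0.163) lay below 2 of the SECIS2 deletion libraries (0.329 and 0.457), and the line's exact permutation p was 0.3. At the peak around nucleotide 1646, the 3 central positions held 92.0%, 83.0% and 59.7% of the counts at nucleotides 1530 to 1703 in SECIS2 wild type. In the SECIS2 deletion they held 6.41%, 38.5% and 70.3%, so the groups overlap. Nucleotide 1658 held 55, 19 and 240 counts in SECIS2 wild type and 1752, 1049 and 287 in the SECIS2 deletion. In SECIS2 wild type replicate 3, nucleotide 1646 held 232.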
